A study of Homo sapiens with 4 samples.

How the data were processed

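Total RNA from MCF10A and MDA-MB-231 cells transfected for 48 h with control or FOXF2 siRNA at 20 nM was measured on Illumina expression BeadChips, with biotinylated cRNA made by a MessageAmp kit, per the labels. There were 4 arrays, 1 per combination of line and siRNA. The labels name no separate cultures, so p-values rest only on the spread between these arrays. In the main fit that spread was taken from genes of similar brightness and not from each gene itself.

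The values used were the authors' processed table, as deposited: 1 linear intensity per gene name and array, for 37810 names. The 4 columns had median intensities of 112, 111, 112 and 112 and mean intensities of 398, 399, 397 and 397, in the order MCF10A control, MCF10A FOXF2 siRNA, MDA-MB-231 control and MDA-MB-231 FOXF2 siRNA. Their quantiles were nearly the same on all arrays, and the lowest values were 72.4 to 74.0, so that no background appeared to have been subtracted. The method by which the authors normalized the values, and how they summarized probes per gene, are not given in the sources used here. A probe-level table was not used: its 8 columns of per-sample values (4 signal columns and their detection p-values) carry numbers that match no sample's labels, so none could be given to a sample by name. No array position or scan information was used, and slide or scan effects were not tested.

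The design had foreseen limma's neqc with detection p-values. As neither control probes nor detection p-values could be assigned, the background of each array was taken as the mode of its values below 140 (kernel density, bandwidth 1.5), with the SD of values below the mode. The modes were 102 on each array and the SDs 8.20, 8.26, 8.15 and 8.17. Each array was corrected with limma's normexp signal estimate at these values, 16 was added and log2 taken. Since the deposited quantiles already agreed, no further normalization between arrays was done. A gene was called above background on an array above the upper 1% of that background (intensities of 121, 122, 121 and 121). Where 1 of 2 arrays compared was above it, the difference was a bound against the lowest value above background on the other array or the gene's own value, whichever was higher, and genes above background on neither array were not called. Such bounds are on the background-corrected scale and depend on that correction. Signal limits precision at the dim end: the robust SD of log2 differences was 0.42 in MCF10A and 0.43 in MDA-MB-231 at a mean log2 value of 6 to 8, and 0.25 and 0.30 at 10 to 16.

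Within a line, with 1 array per group, differences were described by a fixed size of 2-fold. Responses of the lines were compared over genes above background on all 4 arrays. The effect of FOXF2 siRNA averaged over the lines, and the difference between lines, were tested over 20749 genes above background on at least 1 array, with limma 3.58.1 in R 4.3.3 (lmFit with cell line and siRNA, 1 residual degree of freedom, eBayes with a trend, Benjamini-Hochberg adjusted p under 0.05, and a log2 difference of 1 or more between lines). The estimated prior degrees of freedom were infinite. The median prior SD was 0.40. Gene names are those of the deposited table: 15704 matched a current symbol and 2997 a unique synonym in the reference gene table, and 19109 neither.

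The 23 gene lists were described by their median log2 difference over members above background on at least 1 array of the comparison, taken over measured values, and by the percentile of that median among 10000 random lists matched on mean expression in 20 bins, with a bootstrap interval from 2000 resamples of the members. The genes named were chosen by rule: FOXF2, the 12 highest and 12 lowest in each line among genes above background on both arrays, 3 bounds in each direction, up to 4 members per list, the 8 most different responses in each direction, the 10 strongest in each direction of the limma test across lines, and, between lines, 12 and 5 bounds in each direction. Names without an approved-style symbol were counted and not named, and a few genes that the rule selects are not reported here. Genes listed with the tests of the closing section, and those given there as further limma genes, were chosen after their values were seen.

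The tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The background estimate and the limit above background were chosen afterwards: limma's normexp with a background mean fitted to all values was run first and its calls were seen, and it is kept as an added alternative. Also added were a limit at the upper 0.1% of the background, each gene's own spread in limma, and a 1.5-fold difference in the same direction in each line. Settings chosen in advance were no background correction, an offset of 50, scaling to a common median, quantile normalization within each line, a limit at the upper 5% (in place of a looser detection p), no filter on dim genes, bounds left out, 1.5-fold, eBayes without a trend, a log2 difference of 1 in the shared test, cell line alone, and leaving out each array.

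The procedure was tested on simulated arrays with 200 changed genes and an assumed noise. For an effect shared by both lines, limma called 86 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, and 12 of 14936 unchanged genes. The size rule in the MCF10A pair called 52 and 92 of 100, and 20 of 12375 unchanged genes. These rates hold for the simulated arrays and their assumed noise only. The simulated limma test covered 15136 genes, against 20749 genes in the limma test of the measured arrays. How many genes are missed or wrongly called on the measured arrays was therefore not tested.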

Results

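FOXF2 is a forkhead transcription factor best known from mesenchymal tissues. It was depleted with small interfering RNA (siRNA) in 2 breast epithelial lines, to find the genes it regulates in normal-like and in metastatic cells. MCF10A is an immortalized, non-tumorigenic mammary epithelial line, and MDA-MB-231 is a metastatic breast cancer line. Each line received control siRNA or FOXF2 siRNA at 20 nM, and RNA was taken after 48 h. Each of the 4 cultures was read on 1 Illumina BeadChip array, so every group held 1 array and no spread between replicates could be measured within a line. Differences between the siRNAs within a line were therefore ranked by size and not tested, and the number of arrays limits the precision of every value. The deposited intensities covered 37810 gene names. In MCF10A, 13979 of them were above background with control siRNA and 13921 with FOXF2 siRNA, and in MDA-MB-231 the numbers were 14120 and 14030. Across genes above background on all 4 arrays, log2 values of the 2 arrays of a line correlated at Pearson r = 0.982 in MCF10A and 0.981 in MDA-MB-231, and arrays of different lines at 0.909 to 0.914.

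FOXF2 itself was lower with its siRNA in both lines, and all 4 of its values were above background. Its intensity was 241 with control siRNA and 143 with FOXF2 siRNA in MCF10A, a log2 difference of -1.45. In MDA-MB-231 it was 259 and 123, a log2 difference of -2.25. The value of 123 was barely above the background limit of 121, so a deeper fall than in MCF10A was not resolved. With the arrays of both lines in 1 limma model, FOXF2 fell by 1.85 on the log2 scale (SE 0.33, adjusted p = 3.31e-05), lower in 2 of 2 lines; this call was lost when limma ran without a trend or with each gene's own spread. The 16 forkhead genes above background in each line had a median difference of -0.11 in MCF10A and 0.03 in MDA-MB-231. Beside FOXF2, FOXP4 was higher by 0.77 in MCF10A, and FOXO4 and FOXC1 had differences of -0.76 and -0.70 in MDA-MB-231. The size of the FOXF2 difference depended on the background level, since without background correction it was -0.75 in MCF10A and -1.08 in MDA-MB-231.

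In MCF10A, genes above background on both arrays were ranked by their ratio of FOXF2 siRNA to control siRNA on the background-corrected scale. The highest were SFTPD, the lung surfactant protein D gene (intensity 128 to 315, log2 difference 2.46), and GBP2, an interferon-inducible guanylate-binding protein (150 to 382, 2.22). The control intensity of SFTPD was near the background limit of 121, and its ratio of deposited intensities was smaller than that of CLDN1. CFB, encoding complement factor B, was higher by 1.88, PPL, encoding the cornified envelope protein periplakin, by 1.74, and CLDN1, a tight-junction claudin, by 1.64 (342 to 883). DCN, encoding the matrix proteoglycan decorin, was higher by 1.63 (333 to 853). SYT8, CLIC3, YPEL3, SLC43A2, FBXO2 and OPLAH were higher by 1.79, 1.74, 1.69, 1.69, 1.66 and 1.65. Lower with FOXF2 siRNA were the basement-membrane-associated TINAGL1 (-1.93), the spliceosomal Sm protein gene SNRPD1 (557 to 226, -1.76), the retinaldehyde dehydrogenase ALDH1A3 (545 to 237, -1.61) and the gelatinase MMP9 (-1.47). The cytokine gene IL1B had a difference of -1.43 (821 to 360) and the matricellular THBS1, the brightest of these genes, of -1.40 (3117 to 1238). CCDC112, CHRNA9, NSUN6, MOBK1B (now MOB1A) and PRIM2A (now PRIM2, a primase subunit) had differences of -1.75, -1.59, -1.47, -1.43 and -1.41. For genes above background with 1 siRNA only, bounds are given on the background-corrected scale. By them SPSB2 was at least 6.16-fold, HIST1H3F at least 4.04-fold and TJP3 at least 3.66-fold higher with FOXF2 siRNA. RYR3, a calcium release channel, was at least 7.94-fold, MICAL2 at least 3.36-fold and USP46 at least 3.12-fold lower. The deposited intensities differed by smaller ratios, such as 112 to 303 for SPSB2 and 366 to 93.1 for RYR3. In all, 282 genes were at least 2-fold higher and 188 at least 2-fold lower with FOXF2 siRNA in MCF10A, of which 172 and 91 were above background on both arrays. Without background correction the counts were 34 and 9, and the robust SD of the log2 differences over genes above background on both arrays was 0.34.

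Of the gene lists set in advance, 6 had medians in the outer 2.5% of matched random lists in MCF10A, and for 2 of them, mitosis and DNA replication, the bootstrap interval over members stayed there as well. The bootstrap takes members as independent within 1 pair of arrays. It therefore does not measure the spread between cultures for these 2 lists either. Of 29 measured mitosis genes, 27 were lower with FOXF2 siRNA, with a median log2 difference of -0.28, below the medians of all 10000 random lists matched on mean expression. MKI67, the proliferation antigen, had a difference of -0.85, the separase gene ESPL1 of -0.61 and the mitotic kinase AURKA of -0.59 (3993 to 2684), and 3 members reached a 1.5-fold decrease. The 40 DNA replication genes also had a median of -0.28, again below all random lists, with 32 lower. GINS4, a subunit of the replicative helicase complex, was the member at least 2-fold lower after background correction. Its deposited intensities, 236 and 161, differed by less than that. The 24 interferon-stimulated genes had a median of 0.33 at the 99.8th percentile. IFI44 and IFI44L were higher by 1.46 and 1.44, IRF7 by 0.79 and PARP9 by 0.70, and 6 members were at least 1.5-fold higher and none 1.5-fold lower. The 21 fibrillar collagen and matrix genes had a median of 0.32 at the 99.9th percentile, and COL8A1 (782 to 1730, 1.24) and DCN were higher while THBS1 was lower. The 24 epithelial junction and keratin genes had a median of 0.23 at the 98.6th percentile, with CRB3, a polarity protein gene, higher by 0.86 and the desmosomal PKP2 at -0.78. The 24 immediate-early genes had a median of -0.22 at the 0.64th percentile, with EGR1 at -0.58 and IER2 at 0.87. The bootstrap intervals of these last 4 lists reached into the central range, from percentile 93.4 for interferon, 89.8 for matrix and 11.2 for epithelial genes, and up to 80.2 for immediate-early genes, so their positions were not resolved. The matrix and interferon medians were 0.18 and 0.17 without background correction.

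The other lists lay inside the central 95% of matched random lists in MCF10A, and some held members with large differences. Of 22 NF-kappaB targets and cytokines (median -0.13), the chemokine CCL20 had a difference of -1.27 (572 to 288). The mitochondrial superoxide dismutase SOD2 was higher by 1.37 (777 to 1870), and IL6 was at least 1.83 higher on the background-corrected log2 scale. Of the 9 luminal markers (0.13), the mucin MUC1 was higher by 1.46 (1130 to 2952). The 21 matrix proteases and inhibitors had a median of -0.11, and of 19 mesenchymal genes (-0.03) SNAI2 had a difference of -0.79. Medians were 0.18 for CDK inhibitors and p53 targets, -0.22 for the TGF-beta and BMP pathway, -0.06 for G1/S cyclins and E2F factors, -0.12 for basal keratins and hemidesmosomes, 0.04 for the Wnt pathway and 0.30 for the Hedgehog pathway. They were -0.09 for cholesterol synthesis, -0.10 for the unfolded protein and ATF4 response, -0.04 for hypoxia and glycolysis, -0.06 for EGF ligands and receptors (0.12 with the limit at the upper 0.1% of the background) and -0.05 for housekeeping genes. Markers of fibroblasts, endothelium and blood cells, of which 9 were measured, had a median of 0.43 at the 93.9th percentile, with DCN at 1.63 and the endothelial PECAM1 at -0.86.

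Genes above background on both arrays were ranked on the background-corrected scale in MDA-MB-231 as well. HMOX1, the haem-degrading and stress-inducible haem oxygenase, had the highest ratio of FOXF2 siRNA to control siRNA (160 to 538, log2 difference 2.62). CA9, a carbonic anhydrase induced by hypoxia, was higher by 1.58 (162 to 312), TXNIP, an inhibitor of thioredoxin, by 1.38 (249 to 510), and RN7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive, by 1.81 (209 to 514). UCN2, encoding the neuropeptide urocortin 2, was lower (396 to 148, -2.33), as were SSX2IP (364 to 145, -2.24), EDEM1, which directs misfolded glycoproteins to degradation (783 to 299, -1.71), and the chemokine gene CCL11 (-1.60). CEP68, ARHGAP18, TBC1D17, SALL2, FABP6, FLVCR2 and SNCG were higher by 1.84, 1.58, 1.54, 1.51, 1.42, 1.36 and 1.34. STK32C, PADI4, HRIHFB2122 (now TRIOBP), SNRPD1, MOBK1B, ZNF260 and FAM128B (now MZT2B) had differences of -1.69, -1.62, -1.61, -1.58, -1.53, -1.51 and -1.47. Bounds on the background-corrected scale, for genes above background with 1 siRNA only, put NPTXR at least 3.26-fold, ABHD14B at least 3.25-fold and PLD2 at least 2.95-fold higher. By them KIR2DS4 was at least 3.13-fold, EIF2C4 (now AGO4) at least 2.61-fold and CLN8 at least 2.60-fold lower. The deposited intensities differed by smaller ratios, such as 113 to 201 for NPTXR and 196 to 97.8 for KIR2DS4. In all, 201 genes were at least 2-fold higher and 230 at least 2-fold lower with FOXF2 siRNA in MDA-MB-231, of which 104 and 110 were above background on both arrays. Without background correction the counts were 7 and 12, and the robust SD of the log2 differences over genes above background on both arrays was 0.37.

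Of the lists in MDA-MB-231, the immediate-early genes had the lowest median, -0.28 at the 0.09th percentile of matched random lists (bootstrap interval up to 27.95), and 17 of 24 members were lower. The transcription factor genes EGR3 and JUN had differences of -0.94 and -0.67, and IER3 of -0.75 (4952 to 2972). The 29 mitosis genes had a median of -0.18 at the 0.84th percentile (interval up to 5.6) with 23 lower, led by CDC20, an activator of the anaphase-promoting complex (9224 to 4877, -0.93), CDC25C (-0.83), KIF2C (-0.76) and BIRC5 (-0.75). The 20 TGF-beta and BMP pathway genes had a median of 0.25 at the 98.3rd percentile (interval from 5.94 to 99.99), with 12 members higher and 8 lower, and BAMBI, a decoy receptor of that pathway, was higher by 1.07 (435 to 819) and ID2 by 0.94; without background correction the median was 0.12. All 3 intervals reached into the central range, so these positions were not resolved. The DNA replication median was -0.05 and that of the G1/S cyclins and E2F factors -0.18. Among the other lists, the urokinase gene PLAU was lower (14878 to 6207, -1.27) in a protease list with a median of -0.12. The junction genes JUP and PKP2 were higher by 1.31 and 1.13 in a list with a median of 0.09, and the growth factor gene CSF2 was lower (450 to 264) in the cytokine list (-0.15). PPP1R15A had a difference of -1.11 and the endoplasmic reticulum chaperone HSPA5 of -0.90 in the unfolded protein and ATF4 list (-0.10). Medians were -0.10 for CDK inhibitors and p53 targets, 0.01 for mesenchymal genes, -0.14 for basal keratins and hemidesmosomes, -0.07 for collagens and matrix (0.07 with the limit at the upper 0.1% of the background), -0.01 for the Wnt (0.00 with quantile normalization within the line) and 0.07 for the Hedgehog pathway. They were 0.03 for interferon-stimulated genes, -0.17 for cholesterol synthesis, 0.10 for hypoxia and glycolysis, -0.21 for EGF ligands and receptors, 0.28 for luminal markers, 0.36 for markers of other cell types and 0.14 for housekeeping genes.

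**Figure D1:**
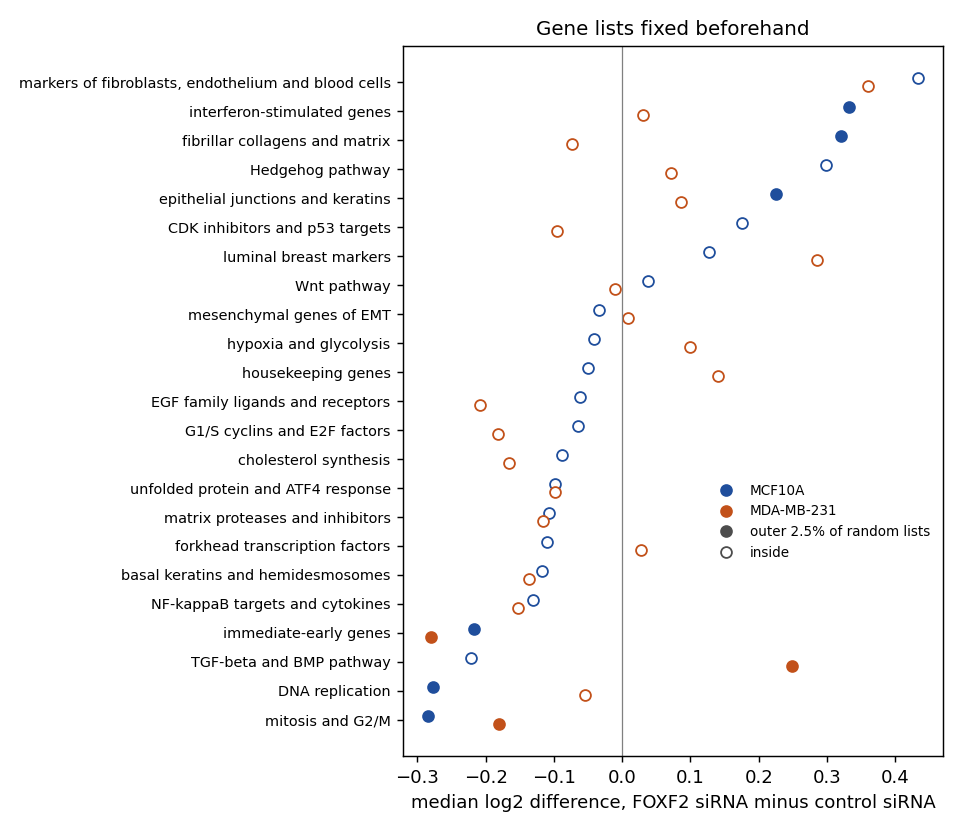
Median log2 difference (FOXF2 siRNA minus control siRNA) of each of the 23 gene lists in MCF10A (blue) and MDA-MB-231 (orange), from 1 array per siRNA and line; filled points lie in the outer 2.5% of random lists on either side. The mitosis list lies at -0.28 in MCF10A and -0.18 in MDA-MB-231.

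To test the effect of FOXF2 siRNA averaged over the lines, the 4 arrays were fitted in limma with cell line and siRNA as terms. Beside FOXF2, SNRPD1 fell by 1.67 (SE 0.24, adjusted p = 1.93e-08), TMED2, a cargo receptor of early secretory vesicles, fell by 1.26 (SE 0.19, adjusted p = 3.19e-07), and ITGA2, the collagen-binding integrin alpha-2 subunit, fell by 1.26 (adjusted p = 5.1e-05). EDEM1, SLC2A3, a glucose transporter, and SSX2IP fell by 1.23, 1.12 and 1.71 (adjusted p = 7.43e-05, 0.0008 and 0.00184), and ALDH1A3 and MOBK1B fell by 1.31 and 1.48 (0.0165 and 0.0278). SPSB2, a substrate receptor of a ubiquitin ligase, rose by 2.03 (SE 0.28, adjusted p = 4.78e-09), HMOX1 by 1.82 (SE 0.31, 2.18e-05) and TXNIP by 1.33 (SE 0.22, 5.4e-06). AKR1C2 and AKR1C4, aldo-keto reductases of steroid metabolism, rose by 1.22 and 1.18 (adjusted p = 3.31e-05 and 2.66e-05); they belong to a family of similar paralogs, and cross-hybridization between its members was not tested. SERPINA5, IFI44L, GCHFR, C1RL and RN7SK rose by 1.44, 1.40, 1.40, 1.31 and 1.21 (adjusted p = 0.0103, 0.0474, 0.00877, 0.0254 and 0.018). PLAU and SOD2, from the protease and cytokine lists, fell by 0.87 and rose by 0.90 (adjusted p = 0.00416 and 0.0312).

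In all, 27 genes rose and 18 fell among 20749 tested with limma, and 1131 had an unadjusted p under 0.05. That number is only slightly above the share of tested genes that such a cutoff passes when no gene changes. The lines stood in for replicates, with 1 residual degree of freedom, and limma set each gene's spread wholly from genes of similar brightness, so that disagreement between the lines did not enter a gene's own p-value. Of the 45 genes, 43 had the same sign in both lines, and the other 2 were GBP2, which differed by 2.22 in MCF10A and -0.18 in MDA-MB-231, and RYR3, which was above background on the MCF10A control array alone. At least 1.5-fold in the same direction in each line were 19 of the genes that rose and 16 of those that fell. Some of the named genes were at background on 1 array (SPSB2, SERPINA5, IFI44L, GCHFR, C1RL, SSX2IP and ALDH1A3), so their fitted changes rest in part on values that are only upper limits. HMOX1 was barely above background on the MCF10A control array (intensity 123.5), and its rise was 1.02 in MCF10A against 2.62 in MDA-MB-231. No gene passed when limma's prior variance did not follow brightness (eBayes without a trend, 980 at an unadjusted p under 0.05, lowest adjusted p = 0.898) or with each gene's own spread (945, lowest adjusted p = 0.278). Both 980 and 945 are below the share that the cutoff passes when no gene changes. Adjusted over the list alone, 3 mitosis genes fell, and none of the 40 replication or 25 immediate-early genes passed; over all genes, none of these did. Passing over all genes were FOXF2 among forkhead genes, S100A4 among mesenchymal genes, PLAU among proteases, SOD2 among NF-kappaB targets, IFI44L among interferon-stimulated genes and SLC2A3 among hypoxia genes. In the same order, adjusted over the list alone, 1 fell, 2 rose and 1 fell, 2 fell, 1 rose, 1 rose and 2 fell. In lists where none passed over all genes, those passing adjusted over the list alone were 3 epithelial genes (rose), 3 matrix genes that rose and 1 that fell, and 1 cholesterol synthesis gene that rose and 2 that fell. The others were 2 unfolded protein and ATF4 genes and 1 basal gene (fell), and 1 TGF-beta and BMP gene and 1 luminal marker (rose).

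**Figure D2:**
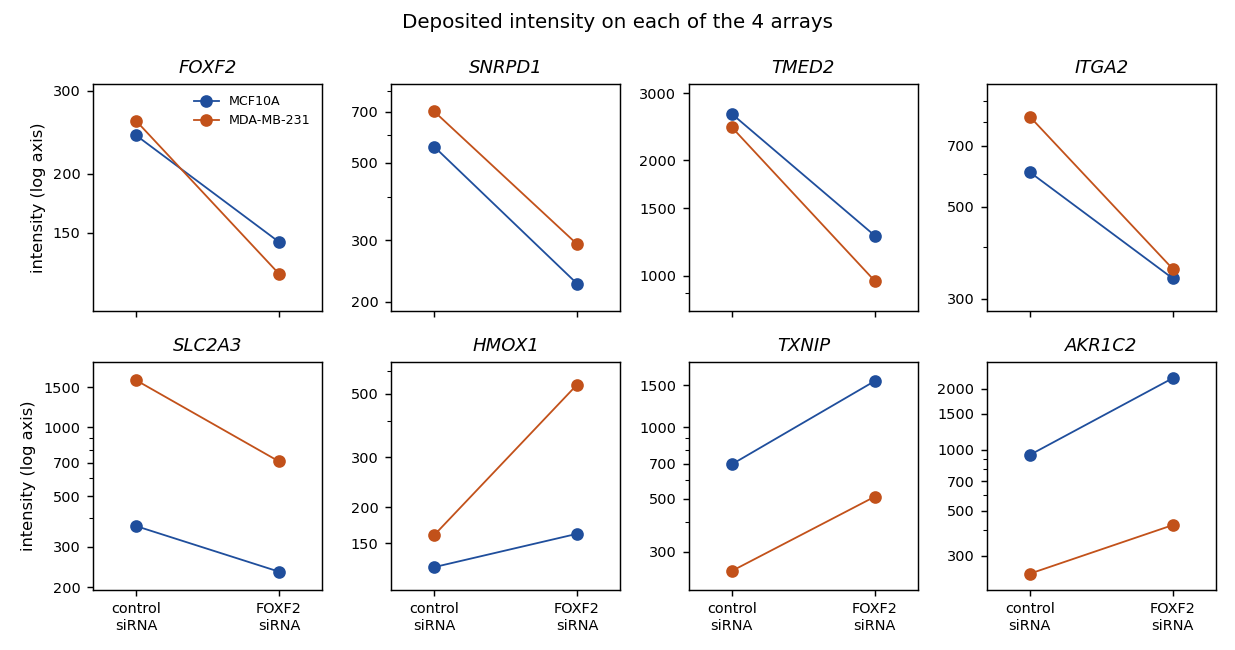
Deposited intensity (log axis) of 8 genes that changed in limma's fit of both lines, on each of the 4 arrays, with lines joining control and FOXF2 siRNA in MCF10A (blue) and MDA-MB-231 (orange); each point is 1 array. FOXF2 was 241 and 143 in MCF10A and 259 and 123 in MDA-MB-231.

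The responses of the 2 lines to FOXF2 siRNA were then set against each other over the 9962 genes above background on all 4 arrays. GBP2 and SLC43A2 were higher in MCF10A and not in MDA-MB-231, so that the MDA-MB-231 response minus the MCF10A response was -2.40 and -2.30 on the log2 scale, and for UCN2, lower in MDA-MB-231 and level in MCF10A, it was -2.32. The receptor tyrosine kinase gene CSF1R and OPLAH differed by -2.01 and -1.93, and KRTDAP, SPIN1 and IPP by -2.26, -2.21 and -2.16. In the other direction ARHGAP18 differed by 2.31, TINAGL1 by 2.14, ZNF77 by 2.14, ZNF121 by 2.10, CCDC112 and NAPA by 2.05 each, the histone methyltransferase gene DOT1L by 1.99 and PKP2 by 1.92. Several of these genes had an intensity close to the background limit of 121 to 122. With FOXF2 siRNA, TINAGL1 was at 123.4 and DOT1L at 122.9 in MCF10A, and IPP at 122.1 in MDA-MB-231. ARHGAP18 was at 121.9 in MDA-MB-231 with control siRNA. Such differences rest on dim values, while GBP2, SLC43A2 and OPLAH lay further above the limit. By list, over members above background on at least 1 array, so that some values lay at background, the response of CDK inhibitors and p53 targets differed by a median of -0.48 (0.07th percentile of matched random lists), that of the TGF-beta and BMP pathway by 0.37 (99.3rd), of DNA replication by 0.18 (98.5th) and of collagens and matrix by -0.26 (2.37th). The bootstrap intervals of all 4 reached into the central range of random lists, up to percentile 65.7 and 20.3 for the first and last and from 60.7 and 71.5 for the others. In all, 531 genes differed at least 2-fold in response, 234 with the MDA-MB-231 response above and 297 with it below. With 1 array per group these differences, by gene or by list, could not be tested, and without background correction 72 genes met the same size rule.

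Across those genes the 2 responses correlated weakly, at Pearson r = 0.125 and Spearman rho = 0.105, as a description over genes that are not independent replicates. Of the genes at least 2-fold lower, 59 in MCF10A and 78 in MDA-MB-231, 8 were lower in both lines. They include FOXF2, the target of the siRNA. Independent lists would share 0.462. Of those at least 2-fold higher, 118 and 82, 4 were higher in both, against 0.971 for independent lists. At 1.5-fold, 82 genes were lower in both lines (31.9 for independent lists) and 79 higher in both (39.7). The numbers for independent lists ignore the larger spread of dim genes, so they may be too small. By the same reckoning 1.41 genes would change 2-fold in opposite directions, and 4 did. No array was shared by the 2 comparisons.

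**Figure D3:**
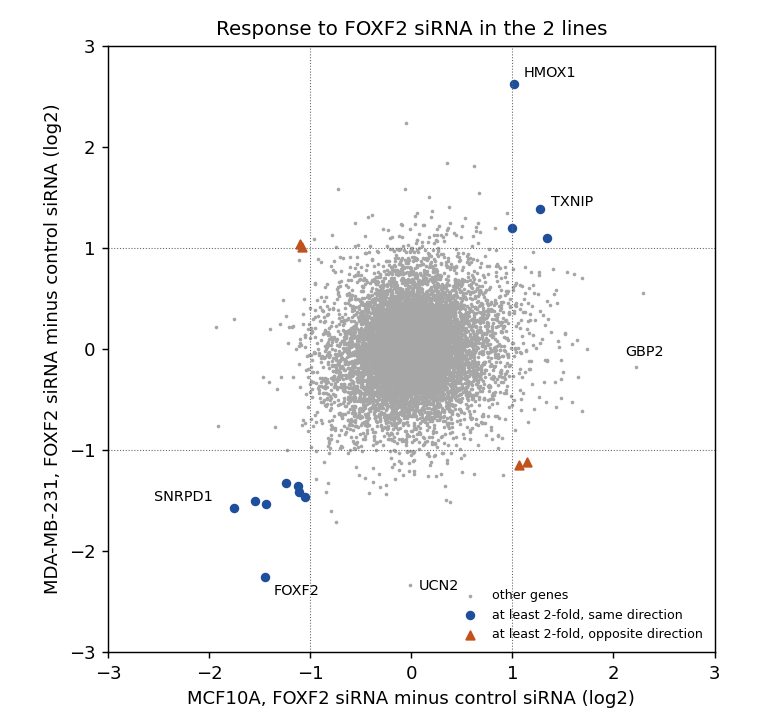
Log2 difference between FOXF2 siRNA and control siRNA in MCF10A (horizontal) and MDA-MB-231 (vertical) for the 9962 genes above background on all 4 arrays, 1 point per gene, with dotted lines at 2-fold. Blue points are the 8 genes lower and 4 higher in both lines by at least 2-fold, and orange triangles the 4 that changed in opposite directions.

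The 2 lines themselves, compared over both siRNAs, differed far more than the siRNAs did. The basal keratins KRT6A, KRT17, KRT5 and KRT6C were bright in MCF10A (KRT6A at 23282 and 24698) and not above background in MDA-MB-231. On the background-corrected scale this made KRT6A at least 683-fold lower in MDA-MB-231. On the same scale in log2, KRT17, KRT5, KRT6C and the calcium-binding S100A8 had differences at or beyond -7.96, -7.62, -7.29 and -7.19. Ratios of the deposited intensities were smaller. Among genes above background on all 4 arrays, IGFBP4, an insulin-like growth factor binding protein, was higher in MDA-MB-231 by 7.76 (SE 0.21), COL13A1, a transmembrane collagen, by 6.41 (SE 0.22), EEF1A2 by 5.66 (SE 0.22) and KLF2 by 5.58 (SE 0.22). SCNN1A, the epithelial sodium channel alpha subunit, was lower by 114-fold (-6.83, SE 0.21), and S100A2 and the squalene epoxidase SQLE had differences of -5.30 and -4.54. EPDR1, above background in MDA-MB-231 alone, was at least 86.9-fold higher there on the background-corrected scale, again with a smaller ratio of deposited intensities. On that scale in log2, COX7B2, the forkhead gene FOXA2, TFF3 and LAPTM5 were higher by at least 6.26, 5.40, 5.30 and 5.17. M160 (now CD163L1), PRSS23, COL6A1, ZNF22, TBL1X, PRKCA, CYR61 (now CCN1) and GFPT2 were higher by 5.17, 4.67, 4.67, 4.28, 4.26, 4.20, 3.95 and 3.71. H2AFY2 (now MACROH2A2), IL20RB, PID1, NNMT, OSBP2, GSTO2, USMG5 (now ATP5MK) and CD24 had differences of -4.94, -4.92, -4.72, -4.48, -4.35, -4.35, -4.32 and -4.22. By limma, 1192 genes were higher and 1237 lower in MDA-MB-231 by at least 2-fold, and 773 and 730 genes were above background on both arrays of MDA-MB-231 or of MCF10A alone. Without the MDA-MB-231 control array 535 and 679 genes passed, without its FOXF2 siRNA array 529 and 689, without background correction 568 and 658, and with each gene's own spread none (2180 at an unadjusted p under 0.05, lowest adjusted p = 0.377).

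Among the lists, 12 of 17 basal keratin and hemidesmosome genes were lower in MDA-MB-231 and none higher (median -1.93). Epithelial junction and keratin genes were lower for 15 of 29 members and higher for 2 (median -1.23), with E-cadherin, CDH1, at 937 and 1105 in MCF10A and not above background in MDA-MB-231, and KRT19 the other way round. Cholesterol synthesis genes were lower for 17 of 22 and higher for none (median -1.79), among them MVD (-2.85), SC4MOL (-2.63) and DHCR7 (-2.31). Of 27 NF-kappaB targets and cytokines, 12 were lower and 3 higher, with CXCL1 at -3.63, and of 23 CDK inhibitors and p53 targets 11 were lower, such as SFN (-2.81), and 3 higher, such as CDKN2D (2.57). Of 31 interferon-stimulated genes, 11 were higher, such as IFI44 (3.39), ISG15 (2.87) and ISG20 (2.57), and 2 lower. Immediate-early genes were higher for 11 of 25, such as FOSL1 (2.67), and lower for 4, among them MYC (-2.93), and 5 of 11 EGF ligands and receptors were higher, such as HBEGF (3.10). Mesenchymal genes went both ways, 5 higher and 9 lower of 23, as did collagens and matrix, 7 and 10 of 24, and proteases, 5 and 7 of 22, where PLAU was higher by 3.40. Adjusted over the list alone, these counts were the same except in the epithelial list, where 16 were lower and 3 higher. Passing in the remaining lists were 4 higher and 1 lower replication genes, 3 and 2 G1/S genes (4 and 2 over the list alone), 1 and 1 mitosis genes, 3 and 4 forkhead genes, 7 and 2 TGF-beta and BMP genes, 4 and 2 Wnt genes, and 0 and 2 Hedgehog genes. There were 2 and 4 unfolded protein and ATF4 genes, 5 and 1 hypoxia genes, 5 and 1 luminal markers, 1 and 2 markers of other cell types, and 2 and 0 housekeeping genes.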

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

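The test in this part was chosen only after the result was seen. In 4 genes the 2 lines moved at least 2-fold in opposite directions with FOXF2 siRNA. The difference between the lines, MDA-MB-231 response minus MCF10A response, was -2.26 for KRTDAP, a keratinocyte differentiation gene, -2.21 for SPIN1, 2.10 for ZNF121 and 2.14 for ZNF77. With 1 array per group, the difference was not tested for any of them. KRTDAP was at 144 and 213 in MCF10A (log2 difference 1.15) and at 167 and 124 in MDA-MB-231 (-1.12), and SPIN1 was at 139 and 196 (1.07) and at 244 and 158 (-1.15). ZNF121 was at 170 and 126 (-1.09) and at 131 and 177 (1.01), and ZNF77 at 180 and 130 (-1.10) and at 149 and 214 (1.04).

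Measurement noise near background is a candidate explanation for these opposite changes. The median of the 4 genes' mean levels lay at the 10.6th percentile (bootstrap interval 6.24 to 16.5) of genes above background on all 4 arrays. Dim genes have the larger spread and pass a 2-fold size cut more often. A low level was therefore likely beforehand, and it does not decide the question. Independent lists of the observed sizes would give 1.41 such genes. A true difference between the lines stays open and was not tested.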

How the results depend on the processing

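Added after the data were seen were the fitted normexp background, the upper 0.1% limit, each gene's own spread and the 1.5-fold requirement in each line. Counts were held to have kept their size within 1.5 times the reported one, FOXF2 and other named differences within the pair's robust SD, list medians within 0.1, and limma genes by their side of the threshold. Scaling to a common median and quantile normalization within each line kept all the values to which they were applied. The deposited quantiles already nearly agreed, so these 2 settings could change little and are a weak check. Under no setting did a called value reverse.

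Without background correction FOXF2 differed by -0.75 in MCF10A and -1.08 in MDA-MB-231, with an offset of 50 by -1.06 and -1.56, and with the fitted normexp by -1.76 in MDA-MB-231. Background handling compresses ratios of dim genes by construction. Genes at least 2-fold higher and lower numbered 34 and 9 in MCF10A and 7 and 12 in MDA-MB-231 without correction, 77 and 27 and then 34 and 35 with an offset of 50, and 105 and 49 and then 54 and 65 with the fitted normexp. With no filter on dim genes they were 905 and 856 and then 840 and 924, with bounds left out 172 and 91 and then 104 and 110, and at 1.5-fold 1330 and 1130 and then 1224 and 1248. With the limit at the upper 5%, 321 were lower in MCF10A and 320 higher and 363 lower in MDA-MB-231, and at the upper 0.1%, 123 were lower in MCF10A and 124 higher in MDA-MB-231. Responses differing 2-fold numbered 72, 202 and 282 without correction, with an offset of 50 and with the fitted normexp, 4396 with no filter and 2261 at 1.5-fold.

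Of genes passing limma's test of the siRNA effect averaged over the lines, 16 rose with no filter, 17 with a log2 difference of 1 required, and 0 rose and 0 fell without a trend or with each gene's own spread; the cause was not tested for the first. Between the lines, 568 were higher and 658 lower without correction and 0 and 0 with own spread, and leaving out each array gave 529 to 874 higher and 679 to 904 lower, with 1 fewer array and the siRNA term dropped. Without a trend or with own spread all shared calls were lost, that of FOXF2 included. Among the named genes, IFI44L, S100A4, RYR3, MOBK1B and C1RL also lost theirs under at least 1 setting of background, offset or limit. The other results gave 3280 values that kept their size, 323 that moved, 31 calls lost and 8 gained.

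The mean over probes of a gene was not run, since only 1 value per gene was used, and the authors' processed values were the same as no background correction. The limma test with a cell line term pairs the siRNAs by line, and there were no replicates to pair within a line, with 1 array per group. Signal near background limits most of these counts.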

Other observations

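The tests of noise near background, of noise independent between the array pairs, of other transcripts as siRNA targets and of an intensity-dependent shift were chosen only after the results were seen, as were the spreads against which the counts and percentiles were judged (the overlap over chance had none) and the genes named in the next paragraph. These spreads moved verdicts toward leaving an explanation open. The lists for ribosome biogenesis, NRF2, differentiation and complement were fixed before their values were seen, but after the genes that prompted them.

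Further genes past the limma threshold and at least 1.5-fold changed in each line included the following. The drug transporter ABCC3 rose in both lines (1.08 in MCF10A and 0.63 in MDA-MB-231, adjusted p = 0.0285), as did the mitochondrial porphyrin transporter ABCB6 (adjusted p = 0.0130) and the ephrin EFNA1 (1.01 and 0.79, 0.0218). S100A4, a calcium-binding protein linked to metastasis, rose by 0.68 and 0.81 (0.0474), and its call was lost under 3 background settings. MCL1, an anti-apoptotic BCL2 relative, had differences of -0.98 and -0.76 (adjusted p = 0.0274), and the cyclophilin PPIC of -1.02 and -0.81 (0.0132).

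Genes lower in both lines with FOXF2 siRNA were more numerous than independent lists would give. The Poisson intervals used here count genes as independent. They therefore cover only noise that is independent between genes as well, and not shifts that move many genes of an array together. Noise of that kind, independent in the 2 pairs of arrays, is argued against. In both lines 82 genes were at least 1.5-fold lower (Poisson interval 65.2 to 101.8). In opposite directions 37 and 33 changed (upper limit 51.0 for the larger). Independent noise is argued against as well among genes brighter than the median of those above background on all arrays. Among these, 20 were 1.5-fold lower in both lines (Poisson interval 12.2 to 30.9) and 2 and 2 changed in opposite directions (upper limit 7.22). As these genes were picked as bright, the counts do not test noise near background, which stays open for the dimmer genes. Of the 16 limma genes at least 1.5-fold lower in each line, 7 were among these brighter genes. Without background correction, 13 of the 16 kept that decrease. Effects of the siRNA on other transcripts and effects of FOXF2 loss cannot be told apart: each line had 1 FOXF2 siRNA group. The labels do not say whether it was 1 duplex or a pool or the same in both lines. The overlap of 2-fold lower genes, 8 with FOXF2 included, was 17.3 times that of independent lists. That of higher genes, 4 in number, was 4.12 times. At 1.5-fold the ratios were closer, 2.57 for lower and 1.99 for higher genes. Both explanations would allow these values. A response to FOXF2 itself therefore remains a hypothesis.

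Mitosis and replication genes were lower with FOXF2 siRNA in MCF10A. An intensity-dependent shift of the arrays is argued against there, since the percentile among random lists matched on mean expression was 0 for the mitosis list and 0 for the DNA replication list. In MDA-MB-231, at percentiles of 0.84 for mitosis and 22.5 for replication, such a shift cannot be told apart, because bootstrap intervals of the medians reach into the range of random lists. Lower growth of the FOXF2 siRNA cultures may be the cause. Ribosome biogenesis genes, taken as other growth genes, lay at percentile 14.2 in MCF10A and 56.2 in MDA-MB-231. By the rule fixed before these values were seen, the MDA-MB-231 position spoke against lower growth. The bootstrap intervals, added later, were too wide to decide, so lower growth stays open. Other differences between the cultures, such as density, were not tested.

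HMOX1 and AKR1C2, which rose in both lines, are known targets of the oxidative stress regulator NRF2, and NRF2 activity may differ with FOXF2 siRNA. In MCF10A the rise of HMOX1 was from 123.5 to 161.6, starting near the background limit. AKR1C4 rose as well, but cross-hybridization with its paralogs was not tested. Of 19 other measured NRF2 targets, 15 were higher in MCF10A, with a median of 0.30 at the 99.97th percentile of matched random lists, among them FTH1 (0.75, 2549 to 4228), EPHX1 (0.85) and AKR1B10 (0.95). This median met the rule fixed beforehand, the upper 2.5%. The bootstrap interval added later, from percentile 90.1 to 100, reaches below that limit. In MDA-MB-231 the median was 0.08 at the 83.3rd percentile, with TXNRD1 at -0.91, so the hypothesis stays open in both lines.

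PPL, KRTDAP and CLDN1 were higher in MCF10A, and a shift toward keratinocyte differentiation may be one reading, though noise near background is also a candidate for KRTDAP. The 15 other measured cornified envelope and differentiation genes had a median of 0.36 at the 96.7th percentile, short of the upper 2.5% set for the test, with SPRR1A at 0.82 and SPRR3 at -0.75. CFB, SERPINA3 (611 to 1480, 1.41) and SOD2 were also higher there, and 12 other complement and acute-phase genes, such as SAA1 (1.14, 685 to 1405) and C3 (0.86), had a median of 0.37 at the 97.1st percentile, again short of it. Both hypotheses stay open.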
